A study of Mus musculus with 2 samples.

How the data were processed

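H3K36me3 ChIP-seq of mouse embryonic facial prominence at embryonic day 15.5 was analysed from the authors' peak lists on mm10. Per the labels, the assay was run on pools of 78 (replicate 1) and 62 (replicate 2) embryos of both sexes, which are separate biological replicates, with 2 and 3 technical replicates, and sequenced on Illumina HiSeq instruments. Per the deposited descriptions, the peaks of replicate 1 and those of the pooled reads were called against 2 control alignments and the peaks of replicate 2 against 1, and the replicated list was derived from the pooled list and both replicates' lists. The aligner, the peak caller, its settings and the rule behind the replicated list are not given in the sources used here. Peaks were therefore called per replicate and, separately, on pooled reads. The lists differ in how strong a control stood behind them, which can change the number of peaks.

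Each peak has the authors' enrichment over control, a linear ratio, and their −log10 p and −log10 q, all taken as deposited in the narrowPeak columns. The lowest −log10 p was 2.00 in replicate 1 and 2.01 in replicate 2. These values belong to a peak within its own list and were used only to describe, rank or filter peaks. No read counts were used, so the depth is unknown and no interval that needs it is given. The signal tracks and alignments that the descriptions name were not analysed here.

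Genes and exons were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, for chromosomes 1 to 19, X and Y, and chromosome lengths from the reference of that assembly (2725.52 Mb in all). For each of 20350 protein-coding genes of at least 2 kb, of 21938 annotated, the covered percent is the share of the body from the first start to the last end that lies in a peak. A gene counted as marked at 10% or more. Coverage measures how much of a gene was called, not the height of the signal, and depends on the calling threshold. Introns are gene sequence outside every exon of any transcript of the gene, and promoters reach 1 kb either side of the gene's start. The annotated features were compared with their share of the genome and with 100 circular shifts of the peaks of replicate 2 along each chromosome. Overlap between lists means at least 1 bp unless stated. The profile used marked genes of at least 5 kb with 10 bins per gene and 1 kb bins in flanks of 5 kb.

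The 32 gene lists, covering housekeeping, cell types of the face, other organs, gene families and chromosome X, were fixed before the data were examined. Members that are non-coding or under 2 kb were left out, as were several globin, small histone and epidermal genes. Each list's mean was compared with 10000 random lists of the same size matched on 10 bins of gene length, in each replicate apart, with a two-sided empirical p and Benjamini-Hochberg adjustment over 32 lists. A list was called only with an adjusted p under 0.05 and the same direction in both replicates. The list of histone genes was picked by symbol and includes H1f0, which is not tied to replication.

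Named genes followed a rule fixed before the data were examined: up to 4 highest and 3 lowest members of each list by mean, the 20 genes of at least 10 kb with the highest value in their lower replicate, the 5 longest runs of replicated peaks with gaps up to 3 kb closed, the 5 longest such runs outside genes, and the 10 genes of at least 10 kb that differed most between replicates after both lists were limited to the same number of peaks by the authors' p. Ties were broken by symbol, so where many members of a list had no peak, only some of them are named. Genes that overlap another coding gene, or have near-identical copies, are uncertain.

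Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots Matplotlib 3.10.9. Interval functions and the random-list test were tested on simulated data. With covered percents of 20350 real genes and 200 random lists of 25 genes, 3.5% passed an unadjusted p of 0.05 with nothing added, 17.5% with 5 points added to each member and 67.0% with 10 points added. These runs used replicate 1 only and fewer random draws than the main test. Their lists were drawn from the same genes as the random lists, so they check the calculation and not lists of neighbouring or overlapping genes.

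The alternatives were a −log10 q of at least 2, each replicate alone, an overlap of at least 50% of both peaks, the replicated list, equal peak numbers, gaps up to 1 kb merged, marked at 5% or 25%, genes overlapping another coding gene left out, no length minimum, no length matching, and the share of marked members. The pooled list was added after the data had been seen. A value counted as moved when it changed by at least 1 SD of the replicates, or for a count by more than 1.5 times.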

Results

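Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark that is laid down over the bodies of genes as RNA polymerase II transcribes them, was mapped by chromatin immunoprecipitation sequencing in the facial prominences of mouse embryos of the B6NCrl strain at embryonic day 15.5. The facial prominences are the embryonic tissue that forms the face and jaws. There was 1 group with 2 biological replicates, each a pool of males and females. Replicate 1 came from 78 embryos and 2 technical replicates, and replicate 2 from 62 embryos and 3 technical replicates. The labels name no second tissue, age or treatment, so the comparisons are between genes, regions and replicates within this tissue. With n = 2, an exact permutation test between replicates could not reach p = 0.05, and a spread between replicates is given as an SD. The peak lists give no read numbers, so the sequencing depth behind each is unknown.

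The authors' list held 172007 peaks in replicate 1 and 192867 in replicate 2. These peaks covered 85.7 Mb, or 3.15% of the genome, in replicate 1 and 100.6 Mb, or 3.69%, in replicate 2, a mean of 93.2 Mb ± 10.5 (SD, n = 2). The median peak was 333 bp long in replicate 1 and 334 bp in replicate 2, and the longest peak reached 14078 bp and 17804 bp. The authors' enrichment over control had a median of 2.86 in replicate 1 and 3.00 in replicate 2, and a maximum of 11.8 and 13.4. Of the peaks, 74.3% in replicate 1 and 84.7% in replicate 2 had a −log10 q of at least 2.

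Most peaks were found in both pools. In replicate 1, 76.7% of peaks overlapped a peak of replicate 2 by at least 1 bp, and 65.0% of the peaks of replicate 2 overlapped a peak of replicate 1. When the peaks of replicate 2 were moved along each chromosome by a random distance 100 times, the highest of these shares were 7.34% and 6.50%. The covered sequence of the replicates had a Jaccard index (shared over total bp) of 0.501, against 0.0227 for the highest of the shifted lists. The unshared peaks were weaker and shorter. In replicate 1 their median enrichment was 2.54, against 3.02 for shared peaks, and their median length was 233 bp, against 393 bp. In replicate 2 the medians were 2.77 against 3.32 and 237 bp against 443 bp. When both peaks had to overlap by at least 50% of their length, 38.2% of the peaks of replicate 1 and 34.0% of those of replicate 2 were shared. The mean of these 2 directions of the same comparison was 36.1%.

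The authors also deposited 189730 peaks called on the pooled reads and a replicated list of 110989 peaks. Every peak of the replicated list was also a peak of the pooled list. Of the replicated peaks, 89.1% overlapped a peak of replicate 1, 94.5% overlapped a peak of replicate 2, and 84.2% overlapped a peak of both. This share was 66.3% when all 3 lists were limited to a −log10 q of at least 2. The replicated peaks had a median length of 633 bp and covered 108.6 Mb.

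H3K36me3 lay almost entirely within genes. Protein-coding gene bodies, from the first transcription start to the last transcript end, took up 38.2% of the genome and held 94.7% ± 0.0554 (SD, n = 2) of the covered sequence. Exons held 24.3% ± 0.757 of it, which was 6.89 ± 0.215 times their share of the genome, and introns held 70.4% ± 0.701, which was 2.03 ± 0.0202 times their share. Sequence outside every annotated gene made up 55.2% of the genome and held 4.44% ± 0.0396 of the covered sequence (0.0804 ± 0.000717 times its share). Promoters, taken as 1 kb on either side of each gene's start, were also depleted, at 0.264 ± 0.0171 times their share. For replicate 2, 100 random shifts of the peaks gave between 0.977 and 1.23 times the genome share in exons, between 1.01 and 1.12 in introns, and between 0.964 and 1.26 in promoters, so the values of replicate 2 lay outside the range that placement alone gave.

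Along genes, the mark rose from the start toward the end. In marked genes of at least 5 kb (6890 in replicate 1 and 7376 in replicate 2, where a marked gene has at least 10% of its body covered), each gene was divided into 10 equal bins. The first bin was covered to 4.49% ± 0.474, the fifth to 39.8% ± 2.03 and the ninth to 54.4% ± 2.30 (SD, n = 2). The last bin was covered to 50.9% ± 2.39. The last 5 bins together were covered 2.06 ± 0.0451 times as much as the first 5. The kilobase just upstream of the start was covered to 1.26% ± 0.114. Downstream of the annotated end, coverage was 38.0% ± 2.75 in the first kilobase, 18.3% ± 1.60 in the third and 15.2% ± 1.15 in the fifth, above the 11.8% ± 0.823 of the kilobase farthest upstream.

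**Figure D1:**
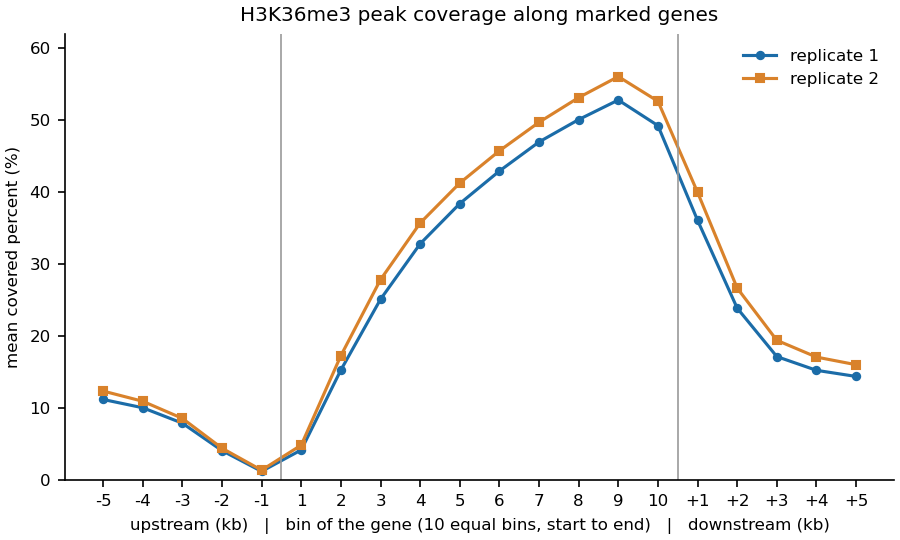
Mean percent of sequence covered by H3K36me3 peaks (vertical axis) over marked protein-coding genes of at least 5 kb, in 5 upstream kilobases, 10 equal bins of the gene and 5 downstream kilobases (horizontal axis), with a line for each replicate. Both lines climb from 4.15% and 4.82% in the first bin to 52.8% and 56.0% in the ninth.

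With bp pooled over all marked genes, exons were covered more than introns. Exons were covered to 48.7% ± 2.18 and introns to 27.3% ± 1.51 (SD, n = 2), a ratio of 1.78 ± 0.0191. Internal exons stood at 54.5% ± 2.25 and last exons at 49.8% ± 2.48, whereas first exons stood at 4.76% ± 0.50. First introns were covered to 6.65% ± 0.532 and later introns to 32.3% ± 1.70. The ratio fell to 1.41 when only genes with at least 25% of the body covered were kept. Exons and introns were not compared gene by gene. Differences between genes in length and coverage could therefore contribute to these values, which was not tested.

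**Figure D2:**
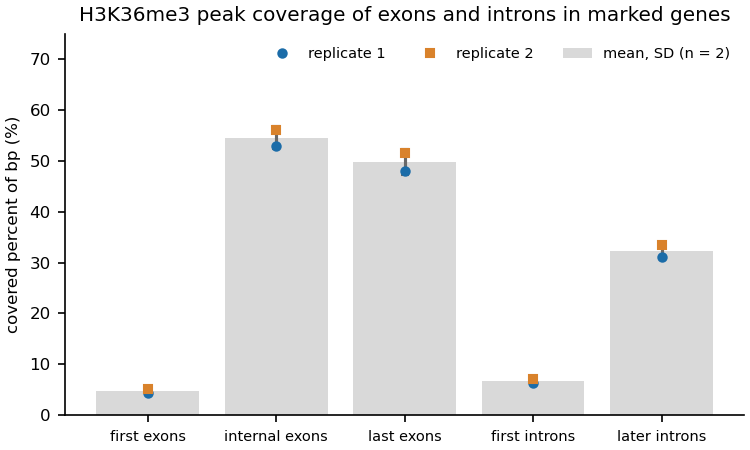
Percent of the bp of each kind of exon and intron in marked genes that H3K36me3 peaks covered (vertical axis). Bars give the mean and error bars the SD of the 2 replicates, which are drawn as points. Internal exons stand at 54.5% and first exons at 4.76%.

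Of 20350 protein-coding genes of at least 2 kb, 7516 were marked in replicate 1, 8034 in replicate 2 and 7392 (36.3%) in both. Independent lists of these sizes would share 2967 genes. Only 124 genes were marked in replicate 1 alone and 642 in replicate 2 alone, and 8346 genes (41.0%) carried no peak in either. Across genes, which are not independent replicates, the covered percent of the replicates had a Spearman rho of 0.965. Genes of intermediate length were marked most often: 45.1% of genes of 10 to 20 kb and 47.6% of those of 20 to 50 kb were marked in both replicates, against 22.8% of genes of 2 to 5 kb and 5.31% of genes of 200 kb or more. A gene without peaks stayed below the authors' calling threshold at an unknown depth, which does not show that the mark was absent. Requiring at least 25% coverage left 4753 genes marked in both.

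Some genes were covered almost end to end. Among genes of at least 10 kb ranked by their lower replicate, the first was Trrap (ENSMUSG00000045482.16, chromosome 5, 144767732 to 144859778), a scaffold of histone acetyltransferase complexes, at 87.7% ± 1.93 (SD, n = 2) of its body. It was followed by the zinc finger gene Zfp110 (86.0% ± 0.957) and by Mybbp1a, a nucleolar transcription regulator (86.1% ± 1.85). The fatty acid synthase gene Fasn reached 85.3% ± 1.06, and Rnf40, part of the histone H2B ubiquitin ligase, 85.9% ± 3.07. The H3K4 methyltransferase genes Kmt2d (84.5% ± 1.40) and Kmt2b (84.8% ± 2.48) were among the 20, as were the splicing genes Sf3b3 (85.2% ± 3.09), Prpf8 (85.3% ± 3.95), Snrnp200 (84.2% ± 2.59) and Ccnl2 (84.0% ± 1.19). The RNA exosome gene Exosc10 stood at 86.2% ± 4.71. The other members were Gtf3c1, Usp36, Prr12, Gm49388, Tcf3, Scrib, Zfp335 and Eif3c, with means between 81.5% and 84.0%. Mybbp1a, Sf3b3, Gm49388 and Zfp335 overlap another coding gene, so their values are uncertain.

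The longest runs of peaks lay over genes. After gaps of up to 3 kb between replicated peaks were closed, 21360 runs remained, with a median length of 3.05 kb, and 268 of them were at least 50 kb long. The longest was 138.7 kb (mm10, chromosome 4, 145051379 to 145190033) and lay in Vps13d. The next was 131.1 kb (chromosome 4, 148452600 to 148583657) across Mtor, the kinase that governs cell growth, with its neighbours Angptl7 and Exosc10. Then came 129.8 kb over Hectd4 and Trafd1 (chromosome 5, 121253723 to 121383536), 122.4 kb over Depdc5 (chromosome 5, 32867212 to 32989604) and 120.6 kb over Wdfy3 (chromosome 5, 101831140 to 101951742). Replicate 1 peaks covered between 46.8% and 72.3% of these runs and replicate 2 peaks between 57.0% and 76.7%.

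Only 399 runs touched no annotated gene, and the longest of these lay beside genes. A run of 11.1 kb (chromosome 12, 108772872 to 108783989) lay 8.98 kb upstream of Yy1. The other 4 lay just past the end of a coding gene: 9.44 kb starting 1.15 kb from Smc5 (chromosome 19, 23195869 to 23205304), 8.47 kb at 0.94 kb from H2-M10.2 (chromosome 17, 36274814 to 36283286), 8.31 kb at 1.23 kb from Trp53inp1 (chromosome 4, 11175610 to 11183924) and 7.72 kb at 0.584 kb from Slc25a40 (chromosome 5, 8455382 to 8463099).

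Gene lists fixed before the data were examined were compared with 10000 random lists of genes of the same lengths in each replicate (two-sided empirical p, Benjamini-Hochberg adjusted over 32 lists). The test compares genes within a library, and genes are not independent replicates. Of the 32 lists, 7 were covered more than random genes in both replicates, 21 less, and 4 passed in neither direction. The smallest p the draws could give was 0.0002, which after adjustment is 0.000427 in replicate 1 and 0.000356 in replicate 2.

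Genes that every cell uses were covered more than random genes. Ribosomal protein and translation factor genes were covered to 45.2% ± 4.40 (SD, n = 2), against 12.3% for random lists, and 24 of 26 were marked in both replicates. The highest were the translation factor gene Eif4g2 (78.7% ± 3.59), Rps5 (74.0% ± 6.29) and Rps3 (73.1% ± 3.68), and the lowest were Rpl10a (15.5% ± 10.1) and the X-linked Rps4x (8.64% ± 3.52). Housekeeping genes were covered to 38.4% ± 2.40 against 16.3%, with 27 of 31 marked. The glycolytic gene Gpi1 (76.2% ± 2.97), the elongation factor gene Eef2 (75.2% ± 5.36) and the chaperone gene Hsp90ab1 (74.4% ± 2.26) led, and the X-linked Hprt (3.67% ± 1.42) and Ubb (0% in both) were lowest. The 7 measured hosts of small nucleolar RNAs, led by Ncl (69.0% ± 6.10), were all marked, at a mean of 49.7% ± 3.39 against 15.2%. Adjusted p was at most 0.00202 for these lists in replicate 1 and 0.000356 in replicate 2.

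Proliferation genes were covered to 44.2% ± 4.00 (SD, n = 2) against 17.6% for random lists, and 25 of 27 were marked in both replicates. The replication licensing genes Mcm2 (71.5% ± 0.411), Mcm3 (70.3% ± 3.02) and Mcm5 (68.6% ± 1.47) were highest, and Ncapg (9.52% ± 2.66), which overlaps another coding gene, and the cyclin gene Ccnb1 (7.78% ± 1.44) lowest. The enzymes and readers of H3K36 methylation were themselves marked in 25 of 27 cases, at 39.6% ± 3.80 against 14.2%. The demethylase gene Kdm4a reached 83.3% ± 3.20 and the reader gene Glyr1 83.0% ± 3.54, whereas Kdm2b, which overlaps another coding gene, stood at 7.35% ± 1.25 and Riox1 at 0% in both replicates. Both lists were at the smallest adjusted p in both replicates.

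Connective tissue matrix genes stood out among the tissue-specific lists. Their mean was 30.4% ± 3.97 (SD, n = 2) against 13.8% for random lists, and 21 of 31 were marked in both replicates. Col6a1 (ENSMUSG00000001119.7, chromosome 10, 76708792 to 76726168), a collagen VI chain, was covered to 74.5% ± 2.64, and its partner Col6a2 to 59.0% ± 0.403. The fibronectin gene Fn1 reached 66.8% ± 8.22 and the collagen chaperone gene Serpinh1 59.1% ± 0.00899. The lowest were the X-linked Bgn (7.44% ± 4.17), Fbln5 (7.37% ± 3.47) and Col14a1 (2.14% ± 1.57). This list, which also holds the receptor genes Pdgfra and Pdgfrb, was at the smallest adjusted p in both replicates as well.

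Bone genes passed in neither direction, with a mean of 9.50% ± 0.634 (SD, n = 2) against 13.8% and only 4 of 23 marked. Those 4 were the type I collagen genes Col1a1 (66.7% ± 1.66) and Col1a2 (54.5% ± 6.99), Sparc (55.1% ± 2.19) and the parathyroid hormone receptor gene Pth1r (20.9% ± 0.274). Pth1r overlaps another coding gene. The osteoblast regulator Sp7 and the bone matrix gene Spp1 had 0% in both replicates. In the random-list test the adjusted p of this list was 0.368 in replicate 1 and 0.284 in replicate 2. Cartilage genes were covered less than random genes, at 3.76% ± 0.729 (SD, n = 2) against 14.2%. Only Fgfr3 (36.9% ± 1.71), Chad (18.9% ± 9.69) and Col2a1 (11.7% ± 0.921) of 26 were marked in both, and the cartilage regulator Sox9 had no peak. Chad overlaps another coding gene. Adjusted p was 0.00291 and 0.00427, but the list passed no longer when the share of marked members was tested in place of mean coverage.

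Transcription factor genes of the facial mesenchyme were covered less than random genes of their length. Their mean was 3.97% ± 0.398 (SD, n = 2) against 11.9%, and 7 of 57 were marked in both replicates. Gli1, a transcription factor of the hedgehog pathway, was highest at 42.0% ± 5.66, ahead of Snai1 (23.3% ± 7.65), Gli2 (22.8% ± 2.86) and Six4 (19.3% ± 4.87). No peak lay in 27 of the genes in replicate 1 and in 29 in replicate 2, among them Tfap2b, Tfap2c and Twist1 in both. Adjusted p was 0.000753 and 0.000356. The 38 measured Hox genes, which pattern the body axis behind the face, carried no peak at all in either replicate and were at the smallest adjusted p in both. Ligands, receptors and other genes of craniofacial signalling were near random lists at 13.7% ± 2.11 (SD, n = 2) against 14.9%, with 12 of 29 marked. In this list the hedgehog receptor gene Ptch1 (45.9% ± 3.61), Tgfb3 (46.2% ± 8.08) and Ctnnb1 (38.3% ± 1.73) were covered, while the ligand genes Shh, Wnt3 and Wnt9b had no peak. Its adjusted p was 0.675 and 0.897. Gli1, Tgfb3 and Ctnnb1 overlap another coding gene.

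Most measured genes typical of muscle, epithelium, nerve, pigment, vessels and blood were not marked. Skeletal muscle genes averaged 0.864% ± 0.0881 (SD, n = 2), and only the calcium pump gene Atp2a1 (14.6% ± 3.51), which overlaps another coding gene, was marked of 33. Surface and oral epithelial genes averaged 5.20% ± 0.765, with 4 of 34 marked, namely Jup (45.5% ± 1.20), Esrp2 (32.9% ± 0.531), Prss8 (19.1% ± 5.66) and Dsp (17.2% ± 4.33). The 13 late epidermal genes had no peak. Neuronal genes averaged 0.0522% ± 0.0318 with none of 29 marked, and melanocyte genes 0.481% ± 0.210 with none of 10. Erbb3 (17.9% ± 3.00) was the only marked gene of 17 Schwann cell and glial genes (mean 1.44% ± 0.112). Endothelial genes averaged 2.70% ± 0.102, with Eng (23.1% ± 2.20) and Ramp2 (13.5% ± 2.69) marked of 18. Erythroid genes averaged 2.65% ± 0.513, with Tmcc2 (20.0% ± 3.90) and Nfe2 (10.3% ± 0.215) marked of the 13 measured. The fixed list held 20 erythroid genes, and several globin genes were among those left out. Leukocyte genes averaged 2.15% ± 0.238, with Fcer1g (18.5% ± 0.221) and Cx3cr1 (15.5% ± 1.69) marked of 21. Esrp2, Prss8, Eng, Ramp2 and Cx3cr1 overlap another coding gene. When genes that overlap another coding gene were left out, the mean was 0.625% for endothelial, 1.13% for leukocyte, 0.478% for skeletal muscle, 0.0475% for melanocyte, 1.13% for Schwann cell and glial, 4.05% for epithelial and 2.90% for erythroid genes, and each list still passed. All these lists were lower than random genes in both replicates, with adjusted p of at most 0.00498 in the random-list test. The erythroid list passed no longer when the share of marked members was tested.

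Genes of other organs had almost no coverage. No member was marked among 23 liver, 16 heart, 16 gut and pancreas, 21 germline and 13 pluripotency genes, whose means lay between 0.0444% and 0.917%. None of 997 olfactory receptor genes had a peak, and 1 of 266 vomeronasal receptor genes, Vmn1r79 (3.31% in replicate 2 and 0% in replicate 1), did. The 10 histone genes of at least 2 kb had a mean of 0.0441% ± 0.0624 (SD, n = 2) and none was marked. All of these lists were lower than random genes, with adjusted p of at most 0.0219. Without genes that overlap another coding gene, liver and gut and pancreas genes had no coverage and heart genes a mean of 0.00625%. The histone list passed no longer without genes that overlap another coding gene, or when the share of marked members was tested.

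Zinc finger genes, picked by symbol and including near-identical copies that can share reads, were covered to 28.3% ± 2.49 (SD, n = 2) against 17.6% for random lists, and 267 of 385 were marked in both replicates. The highest were Zfp869 (95.0% ± 0.354), Zfp110 (86.0% ± 0.957) and Zfp335 (83.1% ± 2.27). No peak lay in 65 of the genes in replicate 1 and in 61 in replicate 2, among them Zfp992, Zfp993 and Zscan10 in both. This list was at the smallest adjusted p in both replicates. The clustered protocadherin genes, whose annotated bodies overlap, averaged 10.2% ± 1.42 against 8.68%, with 21 of 57 marked, and imprinted genes averaged 14.3% ± 1.1 against 14.1%, with 10 of 25 marked. The imprinted genes Nnat (57.2% ± 2.66), Igf2r (44.4% ± 2.17), Impact (40.2% ± 3.49) and Peg3 (36.4% ± 5.79) led, and Magel2, Ndn and Slc22a18 had no peak. Nnat overlaps another coding gene. Neither list passed the random-list test, with adjusted p of at least 0.386.

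**Figure D3:**
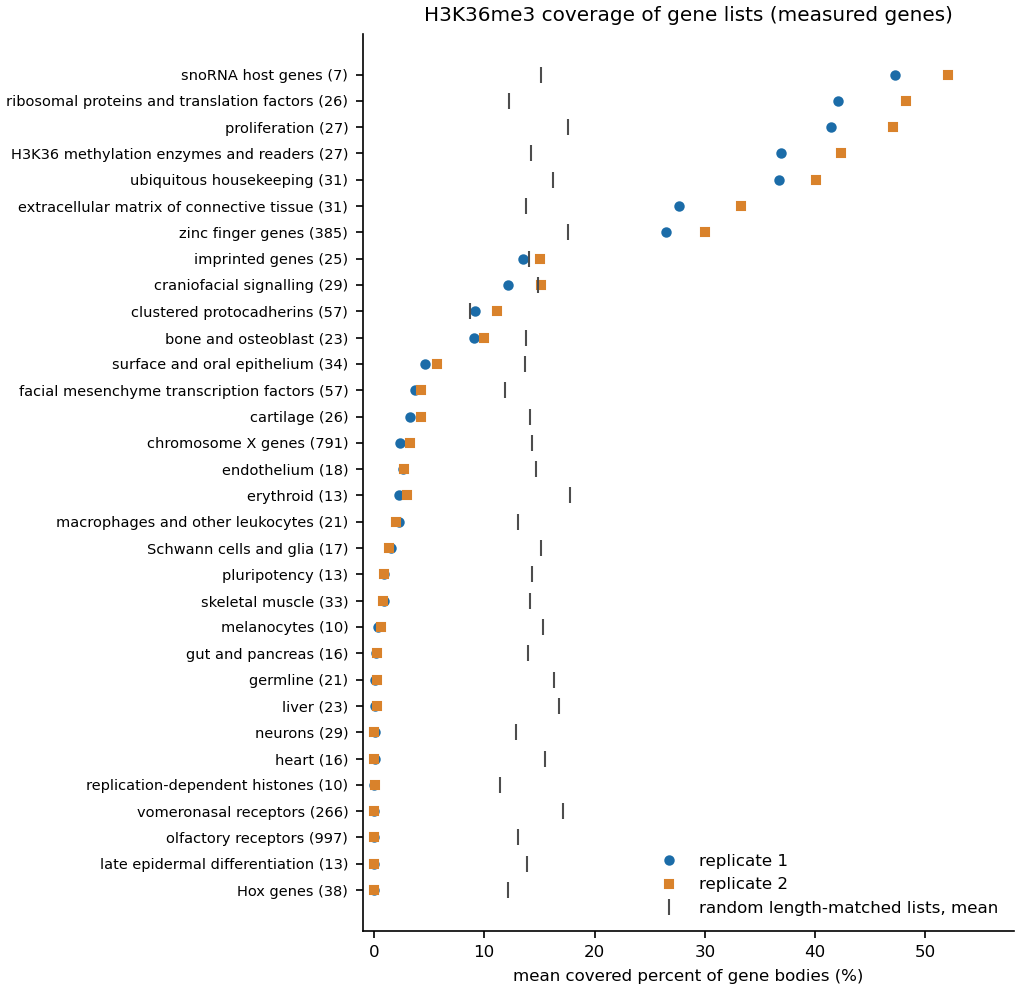
Mean percent of the gene body covered by H3K36me3 peaks (horizontal axis) for each of the 32 gene lists (vertical axis, number of measured genes in brackets). Points give the 2 replicates, and the vertical ticks give the mean of 10000 random lists matched on gene length. The small nucleolar RNA hosts lie highest at 47.3% and 52.1%, and the Hox and olfactory receptor genes lie at 0%.

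Genes on chromosome X had low peak coverage. Its 791 protein-coding genes were covered to 2.84% ± 0.618 on average (SD, n = 2), against 15.4% ± 1.34 for 19408 autosomal genes, a ratio of 0.183 ± 0.0242. Only 64 X-linked genes (8.09%) were marked in both replicates, against 37.8% of autosomal genes. The cytoskeletal gene Flna (57.6% ± 8.47), the transcription cofactor gene Hcfc1 (45.4% ± 6.78), the demethylase gene Kdm5c (43.9% ± 3.89) and Maged1 (42.2% ± 20.0) were covered most. No peak lay in 541 of the X-linked genes in replicate 1 and in 515 in replicate 2, among them Zfp92, Zic3 and Zxdb in both. In both replicates chromosome X lay below each of the 19 autosomes, of which chromosome 14 was lowest (10.8% ± 1.13) and chromosome 8 highest (19.3% ± 1.57). In the random-list test X-linked genes were at the smallest adjusted p in both replicates.

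**Figure D4:**
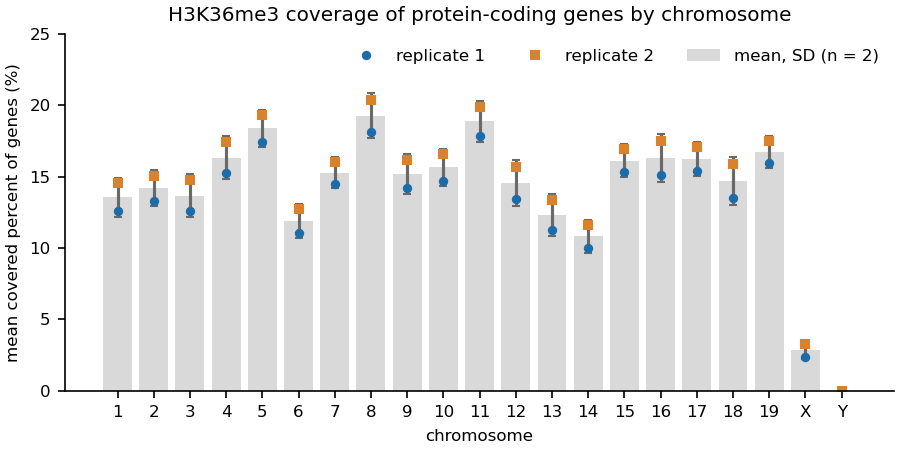
Mean percent of protein-coding gene bodies covered by H3K36me3 peaks (vertical axis) on each chromosome (horizontal axis). Bars give the mean and error bars the SD of the 2 replicates, which are drawn as points. Chromosome X stands at 2.84%, below the lowest autosome at 10.8%.

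Some genes were covered differently in the replicates. After both lists were limited to their 172007 most significant peaks, 448 of 14164 genes of at least 10 kb were covered more in replicate 2 by over 10 percentage points and 30 more in replicate 1. Among the 5964 genes marked on average these numbers were 442 and 30, and the median difference (replicate 2 minus replicate 1) was 3.17 points. The largest differences were in Vamp3 (32.0% against 54.2%), Nme1 (40.2% against 61.0%), Gmnn (13.9% against 34.7%) and Hddc2 (16.0% against 36.5%), all higher in replicate 2, and in Haus5, which was higher in replicate 1 (60.0% against 39.3%, or 47.5% in the full list of replicate 2). Flad1, Cox6c, Tk1, Ccnb2 and Pcdh18 were higher in replicate 2 by 19.1 to 20.0 points. Vamp3, Nme1, Flad1, Cox6c and Tk1 overlap another coding gene. These differences rest on 1 peak list per pool, so they were not tested.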

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

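Some peaks in both replicates lay where few or no genes were measured, which is why they are given here. Whether they exceed a background was not tested. On sequences outside the assembled chromosomes, some of them assigned to a chromosome but without a position on it, there were 19 peaks in replicate 1 and 39 in replicate 2. Such peaks count in the peak totals, but these sequences hold none of the measured genes. On chromosome Y, whose genes were measured but not set against those of X or the autosomes, there were 7 peaks in replicate 1 and 9 in replicate 2, and none of its 151 protein-coding genes was marked in both. All of the chromosome Y peaks of replicate 1, and most of those of replicate 2, lay between positions 90719535 and 90745827.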

How the results depend on the processing

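The pooled list was tried only after the data had been seen. The 7 higher and 21 lower gene lists kept their direction and call, and the other 4 stayed uncalled, under the stricter threshold, equal peak numbers, no length matching, and the replicated and pooled lists. When the share of marked members was tested, cartilage (15.4% of members), erythroid (15.4%) and histone (0%) genes passed no longer, and without overlapping genes the histone list (0%) did not pass either, while no protocadherin gene remained to test. The causes were not tested. With a −log10 q of at least 2, gene bodies held 95.0% of covered sequence, the ratio of last to first 5 bins of genes was 2.13, the ratio of chromosome X to autosomes 0.153, and the share of replicated peaks found in both replicates 66.3%. With 50% overlap, the shared share, averaged over both directions, was 36.1% and that of replicated peaks 42.0%. Gene bodies held 94.9% with the replicated list, 94.8% with equal peak numbers and 94.4% with the pooled list, whose other ratios were 1.93 along genes, 1.76 for exons over introns and 0.231 for chromosome X. The exon to intron ratio was 2.02 in genes marked at 5%, 1.41 at 25% and 1.76 without overlapping genes, and at 25% the ratio along genes was 1.95 and 4753 genes were marked in both. No call changed direction. No paired analysis was possible because there is 1 group. Of 252 named genes, 9 moved by at least 1 SD with equal peak numbers, 34 under the stricter threshold, 91 with the replicated list and 118 with the pooled list. Many of the 252 had no peak in either replicate. Such genes could not move with equal peak numbers or the stricter threshold, which only remove peaks, so these counts understate how far covered genes moved. Depth is unknown, so weakly marked genes cannot be told from unmarked ones.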

Other observations

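Several non-coding genes were marked as well. They come from members of the gene lists that the main test left out, apart from Malat1, Neat1, Mir17hg, Tug1 and Xist, which were chosen after their values were seen. The small nucleolar RNA host Snhg1 was covered to 60.4% ± 10.4 (SD, n = 2) and Snhg12 to 44.3% ± 2.33. Zfas1 (38.3% ± 6.30), Snhg6 (25.3% ± 3.96), Gas5 (19.6% ± 15.7) and Snhg3 (16.1% ± 4.49), which overlap coding genes, were lower. Of the maternally expressed imprinted cluster on chromosome 12, Meg3 reached 32.2% ± 4.67, Rian 18.5% ± 3.29 and Mirg 37.8% ± 1.78. H19, on chromosome 7, had no peak. Airn stood at 14.1% ± 2.14 and Kcnq1ot1 at 4.81% ± 0.457, but both overlap coding genes. The microRNA host Mir17hg was covered to 45.6% ± 10.8, Malat1 to 41.3% ± 7.09 and Tug1, which overlaps a coding gene, to 60.5% ± 1.58. Neat1 was covered to 3.14% ± 1.62 and Xist, which also overlaps a coding gene, to 0.806% ± 1.14.

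Long intergenic RNA genes were rarely marked. Of 4438 such genes of at least 2 kb that touch no coding gene, 39 (0.879%) were marked in both replicates, against 36.3% of protein-coding genes. Of 2310 antisense genes 386 (16.7%) were marked, but of the 143 that touch no coding gene only 2 were (1.40%).

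The tests on exons and on zinc finger genes were written before their results were seen, apart from the match on GC content and position together, which was not, and the 3 tests on chromosome X were chosen after its low coverage had been seen.

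Exons were covered more than introns in marked genes. Windows of 200 bp were taken over internal exons and over all introns of at least 200 bp. They came from genes marked in both replicates that overlap no other coding gene. First and last exons were left out, but first introns, which were covered little, were kept. The ratio was 2.18 in replicate 1 and 2.02 in replicate 2. It was 2.05 and 1.96 after matching on GC content, and 2.03 and 1.92 in windows free of repeats. After matching on position along the gene it was 1.90 and 1.77. None of these accounts for the whole of this pooled ratio in internal exons. Matched on GC content and position together it was still 1.76 and 1.69. The windows were pooled over genes and never matched on gene, gene length or gene coverage. Differences between genes could therefore keep the ratio high in every version, and they were not tested. No biological explanation was tested.

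The low coverage of chromosome X may have more than 1 source. Whether gene content accounts for it stays open. In the test, 29 widely expressed X-linked genes reached 0.351 (replicate 1) and 0.419 (replicate 2) of the coverage of length-matched autosomal genes. Those 86 widely expressed genes came from the housekeeping, ribosomal, H3K36 methylation and small nucleolar RNA host lists, which were covered more than random genes. The X-linked genes were picked separately, so a low ratio could come from how the genes were chosen. Fewer reads from fewer active copies stay open, since the test of it cannot decide: the ratio of X to autosomes was 0.231 in the list from pooled reads, above 0.166 and 0.201 in the replicates, but such a rise was not confined to X. Over random lists, X-linked genes stood at 0.248 with pooled reads against 0.179 and 0.216. Of 7 other sparsely covered lists, cartilage (0.345 against 0.245 and 0.285) and Schwann cell genes (0.133 against 0.107 and 0.0847) rose by a larger factor, 3 rose above both replicates by a smaller one, and erythroid and leukocyte genes did not rise above both. Silencing of a second X in the female embryos also stays open, as 4 genes known to escape it averaged 26.2% against 12.3% for the other 25 in replicate 1 and 31.1% against 17.0% in replicate 2, with an exact permutation p (two-sided) of 0.0296 and 0.102. Kdm6a, 1 of the 4, was covered to only 2.80% and 3.79%. The sexes were pooled, so their share in this pattern was not tested.

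The strongest peaks lay in zinc finger genes more often than other peaks. Of the 500 peaks of highest enrichment, 97 (19.4%) in replicate 1 and 109 (21.8%) in replicate 2 lay in these genes, against 1.92% and 1.89% of all peaks. Reads shared between listed zinc finger genes do not account for this, since a median of 0.169% and 0.221% of the 36-mers in those peaks occurred in another such gene. Of those peaks, 69.1% and 63.3% overlapped a last exon of a zinc finger gene. Length-matched last exons of other marked genes reached 0.822 and 0.812 of the median highest enrichment, and none of 10000 draws reached the zinc finger median. Length alone thus does not account for the higher median of zinc finger last exons. That median was 4.44 and 4.98, below the 5.72 and 6.51 that the 500 strongest peaks reached at least. The comparison therefore cannot say how many of these peaks long last exons account for. Genes that overlap another coding gene were left out of the other marked genes but kept among the zinc finger genes, so the groups were not filtered alike. Copies outside the list and a biological explanation were not tested.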
